A study of Gallus gallus with 50 samples.

How the data were processed

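Polyadenylated RNA was measured by stranded sequencing in GFP-positive and GFP-negative cells sorted from dissected chicken heads, with about 20 heads pooled for a sample per the labels' protocols. Reads were trimmed with cutadapt 2.10, aligned with HISAT2 2.1.0 and handled with SAMtools 1.9, per the submitters' processing notes. The deposited values are whole-number read counts per gene, made with featureCounts 1.6.2 against the Ensembl release 99 annotation of GRCg6a with reverse-stranded counting, per the file headers. The command in the header sets no option for reads that map to several places or overlap several genes, so reads shared by near-identical genes were not counted and such genes are understated. The deposited tables give each gene's summed exon length, which was used only to describe genes. Coordinates are those of the deposited table on GRCg6a, counted from 1.

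The deposited full table holds counts of 24356 genes in 50 libraries, and the authors' filtered table holds identical counts for 42 of them. The series' design text says that the filtered table leaves out libraries of low quality. The comparisons used the 42 kept libraries. Every column could be matched to a sample through its name. The kept libraries held 4869937 to 29316689 counted reads, and between 11128 and 14725 genes with 10 or more reads. At these depths a gene with 0 reads in a group can still be present below 3 counts over the group, which was the floor for folds against such groups. Floors cover counting error only.

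The population and stage of each library came from the labels, giving 12 groups. The labels do not say that libraries of a group came from separate batches of embryos beyond the pool named in the titles, so p-values measure the spread between these libraries. No pair of libraries in a group agreed within sampling noise, the lowest chi-square per degree of freedom being 8.31. Genes with too few reads were removed with filterByExpr by group, which left 15737 genes and removed 8619. Counts were normalised with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16, with robust dispersion and all 12 groups in one fit. P-values were adjusted by Benjamini-Hochberg, and 0.05 was the threshold. The common dispersion was 0.219. Levels are given as CPM on TMM-scaled library sizes.

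The titles give the GFP-positive and GFP-negative library of one sort a shared name, which was taken as a shared pool of embryos. Whether they deviate together was checked by correlating their deviations from the group means. These correlations were computed before the fits with a block, and were read stage by stage only after those fits had been seen. Every pair correlated above 0.1 at HH6 (0.183 to 0.412), HH8 (0.171 to 0.290), HH12 (0.149 to 0.401) and HH14 (0.293 to 0.664). At HH10 the 2 pairs gave 0.00717 and 0.0921 and at HH16 the lowest of 5 pairs gave 0.0884, so that these stages did not pass the check. Both libraries of every pair also belong to the same sequencing set. The check therefore cannot tell shared embryos from shared sequencing. The pool is taken to stand for shared embryos. The blocked value is therefore given wherever it changes a comparison by over 1.5 times in total or in 1 direction, HH10 and HH16 included. A library without a kept partner adds nothing to the blocked difference, which rests on 2 pairs at HH10 and 3 at HH12. A call lost there with the block may be lost to fewer libraries.

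The comparisons, the test and the rule for named genes were fixed before the data were examined. The rule took the largest rises and falls among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. For the average over stages it asked for the same sign in at least 5 of the 6 stages, and for the change of the difference it asked for neither. Groups of 3 against 3 fail to overlap by chance for 10% of genes. The rule also asked for gene symbols, and the files do not pair the Ensembl identifiers with symbols. Of the 25635 rows of the reference gene table, which is on another assembly, 0 hold an Ensembl identifier. None of the 24356 identifiers could therefore be matched. The condition on symbols was therefore dropped after the data were seen, at most 2 identifiers that rose and 2 that fell are given for each comparison, and the 32 gene lists and cell type markers fixed beforehand were not tested. After the data were seen, 8 groups of genes defined by chromosome, exon number and span were tested with camera and fry on voom values in limma 3.58.1, adjusted within each comparison, with a preset correlation of 0.01 and an estimated one. Neighbouring genes called in the same direction were counted along each chromosome and compared with 1000 shuffles of the calls within chromosomes.

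The alternatives fixed beforehand were all 50 libraries, DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no filter and a filter of 1 CPM in 3 libraries, the pool as a block or, for changes with stage, as a random effect in limma voom, the 4 sequencing sets of the sample table as a covariate, only the compared groups in the fit, a test against a fold change of 1.5, and leaving out each library in turn. Chosen after seeing the data were leaving out the 3 kept libraries with the fewest detected genes, quality weights for each library in limma voom, limma voom without weights or pools, thinning every library to the depth of the shallowest, leaving out chromosomes Z and W, and upper-quartile normalisation. Because 1 of the sets, MR, joins 3 sequencing runs by the descriptions, the 6 runs were also used as a covariate. The 3 libraries with the fewest detected genes were NC_16 replicate 3, WE_10 replicate 2 and WE_16 replicate 5. They held 11506, 11678 and 12498 genes with a read, and the next had 13986. In comparisons that do not use their groups, leaving them out acts only through the fit shared by all groups.

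The test was also run on counts simulated from the real genes' means, dispersions and library sizes, with equal groups apart from a set of changed genes among 15737. For the comparison at HH8, 53.0% of genes changed 4-fold, 10.4% of those changed 2-fold and 0 of those changed 1.5-fold were called. For the average over stages the shares were 89.4%, 62.7% and 37.3%, and for GFP-positive cells between HH6 and HH16 they were 56.1%, 23.9% and 1.49%. False calls made up 2.33%, 3.08% and 5.26% of calls. The simulated libraries were drawn independently, without shared effects of pools or sequencing sets. These shares thus do not measure false calls from such effects. R 4.3.3 and Python 3.11.15 were used.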

Results

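The series profiled polyadenylated RNA from the heads of early chicken embryos at 6 Hamburger-Hamilton (HH) stages, the standard morphological stages of chick development. Embryos had been electroporated with a reporter in which a TFAP2A enhancer drives GFP. Cells were sorted into a GFP-positive fraction, labelled neural crest, and a GFP-negative fraction of the head. Cells without an active reporter were sorted as GFP-negative, whatever their type. No cell type marker was tested, so that the fractions are known by their labels only. Neural crest is a migratory embryonic cell population that forms much of the facial skeleton and peripheral nervous system. The comparisons ask how the GFP-positive fraction differs from the GFP-negative fraction at each stage, and how each fraction changes with stage. The 50 deposited libraries fall into 12 groups. The authors' filtered table keeps 42 of them, with 3 GFP-positive (named NC_ and the stage) and 3 GFP-negative libraries (named WE_ and the stage) at each of HH6, HH8, HH10 and HH14, 4 of each at HH12 and 5 of each at HH16. Kept libraries held between 4869937 and 29316689 counted reads. Libraries of a group correlated across genes with a median Pearson r of 0.952 and a lowest value of 0.850, and genes are not independent replicates. Genes are given by their identifiers because the files do not pair these with names. With all 50 libraries the count of called genes was lower by over 1.5 times in 11 of the 12 comparisons and higher in the other.

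**Figure D1:**
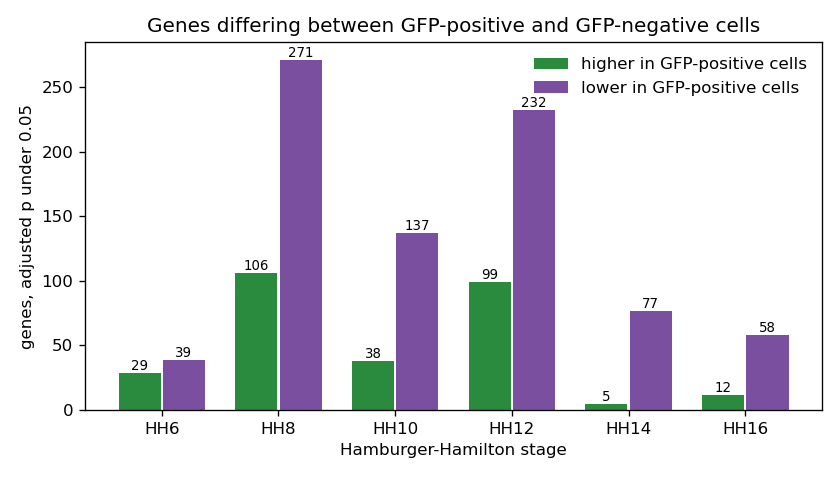
Number of genes (y axis) with an adjusted p under 0.05 between GFP-positive and GFP-negative cells at each stage (x axis), as bars for higher and lower in GFP-positive cells. Lower genes outnumber higher genes at every stage, with 271 against 106 at HH8 and 39 against 29 at HH6, where 16 against 17 were left without NC_6 replicate 2 and 29 against 30 without WE_6 replicate 1. At HH10 it is 137 against 38, and 138 against 129 without WE_10 replicate 3. Over all fits that left out 1 library the share of lower genes ran from 48.5% to 86.4% at HH6 and from 51.7% to 90.5% at HH10.

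At HH6, ENSGALG00000016680 (chromosome 3, 108221189 to 108246601, minus strand) was higher in GFP-positive cells, at 20.0 ± 24.3 CPM against 0.779 ± 0.575 CPM (SD, n = 3 each), a log2 fold change of 4.64 ± 0.82 (SE, edgeR adjusted p = 0.00326). ENSGALG00000041640 (chromosome 2, 29565482 to 29567600) was lower, at 2.09 ± 0.163 CPM against 29.6 ± 15.6 CPM, a log2 fold change of -3.83 ± 0.71 (adjusted p = 0.00408). ENSGALG00000008941 on chromosome 1 was higher, with a log2 fold change of 3.47, and ENSGALG00000027213 on chromosome 1 was lower, at -3.89. In total 68 of 15737 tested genes passed, 29 higher and 39 lower, and 217 passed with the pool of embryos as a block, 95 higher and 122 lower. The count was 36, 33 and 32 without NC_6 replicate 1, 2 and 3, and 44 without WE_6 replicate 3. It was 177 without the 3 libraries with the fewest detected genes, none of them from HH6. Higher genes numbered 18 without WE_6 replicate 2. Over the fits that left out 1 library the share of lower genes ran from 48.5% to 86.4%. The call of ENSGALG00000016680 was lost without NC_6 replicate 3 (adjusted p = 0.0856). That of ENSGALG00000008941 was lost without NC_6 replicate 3 or any WE_6 library (up to 0.539), and that of ENSGALG00000027213 without NC_6 replicate 2 or 3 or WE_6 replicate 1 (up to 0.595). None of the 4 calls passed with limma voom in place of edgeR (adjusted p from 0.227 to 0.533) or with all 50 libraries (0.0658 to 0.521), and only that of ENSGALG00000041640 with the compared groups alone in the fit. That of ENSGALG00000027213 was also lost without a filter (0.0751).

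At HH8, ENSGALG00000043204 (chromosome 21, 4449679 to 4535824) was higher in GFP-positive cells, at 60.3 ± 20.9 CPM against 2.78 ± 1.06 CPM (SD, n = 3 each), a log2 fold change of 4.43 ± 0.58 (SE, edgeR adjusted p = 5.71e-06). ENSGALG00000045684 (chromosome 28, 3528771 to 3530950) was lower, at 0.809 ± 0.482 CPM against 66.5 ± 35.7 CPM, a log2 fold change of -6.32 ± 1.06 (adjusted p = 0.000406). ENSGALG00000035194 on chromosome 22 was also lower, with a log2 fold change of -6.36, and ENSGALG00000051844 on chromosome Z was higher, at 4.99. Of the genes called at HH6, 25 of the 29 higher and 37 of the 39 lower were called in the same direction at HH8, where independent lists would share 0.195 and 0.672. In total 377 genes passed, 106 higher and 271 lower, and 740 passed with the pool as a block, 257 higher and 483 lower. The count was 174, 196 and 166 without NC_8 replicate 1, 2 and 3, and 184 and 248 without WE_8 replicate 2 and 3. It was 750 with the compared groups alone in the fit. It was 705 without the 3 libraries with the fewest detected genes, none of them from HH8. The share of lower genes ran from 62.0% to 85.9% over the fits that left out 1 library. With all 50 libraries none of the 4 calls passed (adjusted p from 0.184 to 0.887). The call of ENSGALG00000051844 was lost without NC_8 replicate 2 or 3 or any WE_8 library (adjusted p up to 0.171).

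At HH10, ENSGALG00000042686 (chromosome 8, 28132665 to 28133855) was higher in GFP-positive cells, at 240 ± 161 CPM against 18.2 ± 6.59 CPM (SD, n = 3 each), a log2 fold change of 3.72 ± 0.73 (SE, edgeR adjusted p = 0.00623). ENSGALG00000016680 was higher here too, with a log2 fold change of 3.31. ENSGALG00000002263 (chromosome 9, 2728404 to 2746826) was lower, at 0.140 ± 0.130 CPM against 10.5 ± 4.91 CPM, and ENSGALG00000016215 (chromosome 1, 112117781 to 112133306) was lower, at 2.32 ± 0.606 CPM against 35.1 ± 12.4 CPM. In total 175 genes passed, 38 higher and 137 lower. With the pool as a block 186 passed, 74 higher and 112 lower, and 84 of the 175 were among them. That fit rests on 2 pairs here, since NC_10 replicate 2 and WE_10 replicate 3 have no kept partner. The count was 14 and 33 without NC_10 replicate 2 and 4, and 63, 267 and 113 without WE_10 replicate 2, 3 and 4. Of the 267, 129 were higher and 138 lower. The share of lower genes ran from 51.7% to 90.5% over the fits that left out 1 library. Each of these 4 calls was lost without NC_10 replicate 2 (adjusted p up to 0.0982 over the libraries left out). Those of ENSGALG00000002263 and ENSGALG00000016215 were also lost without NC_10 replicate 4, that of ENSGALG00000016680 also without WE_10 replicate 2 or 4, and that of ENSGALG00000002263 also with the pool as a block (adjusted p = 0.0638, the others running down to 5.26e-07). With all 50 libraries the calls of ENSGALG00000042686 and ENSGALG00000016680 were lost (0.0651 and 0.0868).

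At HH12, ENSGALG00000042686 was higher in GFP-positive cells, at 159 ± 79.9 CPM against 13.4 ± 9.58 CPM (SD, n = 4 each), a log2 fold change of 3.56 ± 0.62 (SE, edgeR adjusted p = 0.000721). ENSGALG00000016680 was higher, at 282 ± 67.9 CPM against 25.8 ± 10.1 CPM, a log2 fold change of 3.44 ± 0.59 (adjusted p = 0.000523). ENSGALG00000053511 and ENSGALG00000015253, both on chromosome 1, were lower, with log2 fold changes of -4.53 and -4.19. A run of 3 neighbouring tested genes on chromosome 1 between 44000044 and 44202174 was lower. In total 331 genes passed, 99 higher and 232 lower. The count was 153 and 160 without NC_12 replicate 1 and 2, and 194 without WE_12 replicate 2. It was 657 without the 3 libraries with the fewest detected genes, none of them from HH12. Higher genes numbered 53 without WE_12 replicate 1. With the pool as a block the comparison rests on 3 pairs, since NC_12 replicate 3 and WE_12 replicate 5 have no kept partner. The calls of ENSGALG00000053511 and ENSGALG00000015253 were lost with the pool as a block (adjusted p = 0.129 and 0.25) and without NC_12 replicate 1, 2 or 3 or WE_12 replicate 2. The former was also lost without WE_12 replicate 3 (up to 0.123) and the latter also without WE_12 replicate 1 or 5 (up to 0.144). Both were lost with all 50 libraries (0.201 and 0.378), and the latter with limma voom (0.0791).

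At HH14, ENSGALG00000039452 (chromosome 1, 93831630 to 93850776) was lower in GFP-positive cells, at 1.01 ± 0.632 CPM against 39.8 ± 1.6 CPM (SD, n = 3 each), a log2 fold change of -5.31 ± 0.87 (SE, edgeR adjusted p = 0.00135). ENSGALG00000042686 was higher, with a log2 fold change of 3.57 ± 0.72 (adjusted p = 0.0112). ENSGALG00000012290 (chromosome 1, 51055215 to 51064410) was higher, at 407 ± 286 CPM against 49.3 ± 8.13 CPM, and ENSGALG00000039245 on chromosome 1 was lower, with a log2 fold change of -4.67. In total 82 genes passed, 5 higher and 77 lower, and 212 passed with the pool as a block, 29 higher and 183 lower. The count was 14, 29 and 27 without NC_14 replicate 1, 2 and 3, and 23 and 49 without WE_14 replicate 1 and 3. It was 217 without the 3 libraries with the fewest detected genes, none of them from HH14. Without WE_14 replicate 2, 2 genes were higher. The call of ENSGALG00000012290 was lost without any 1 of the 6 libraries (adjusted p up to 0.439). That of ENSGALG00000042686 was lost without NC_14 replicate 1 or WE_14 replicate 1 or 3 (up to 0.177), and that of ENSGALG00000039245 with the block (0.0509) and without any library but WE_14 replicate 2 (up to 0.249). None of the 4 passed with all 50 libraries (0.293 to 0.925). All deposited HH14 libraries were already kept, so that fit added libraries of other stages only. There the log2 fold changes were -5.28, 3.59, 3.07 and -4.64 in the order named above. The calls of ENSGALG00000042686 and ENSGALG00000012290 were lost with the compared groups alone (0.107 and 0.0573), and those of ENSGALG00000012290 and ENSGALG00000039245 without a filter (0.0929 and 0.0578).

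At HH16, ENSGALG00000007646 (chromosome 4, 11924118 to 12042777) was lower in GFP-positive cells, at 3.81 ± 3.85 CPM against 62.9 ± 25.3 CPM (SD, n = 5 each), a log2 fold change of -4.04 ± 0.72 (SE, edgeR adjusted p = 0.00402). ENSGALG00000042686 was higher, at 59.4 ± 16.0 CPM against 13.1 ± 6.35 CPM, a log2 fold change of 2.18 ± 0.53 (adjusted p = 0.0496). ENSGALG00000040730 (chromosome 8, 5512946 to 5535929) was higher, at 50.3 ± 17.6 CPM against 13.2 ± 5.28 CPM, and ENSGALG00000003594 on chromosome 22 was lower, with a log2 fold change of -4.68. In total 70 genes passed, 12 higher and 58 lower, and 152 passed with the pool as a block, 40 higher and 112 lower. A fit holding only these 10 libraries called 0 genes with edgeR, with 631 at an unadjusted p under 0.05. A share of 0.05 of the tested genes would fall there without any difference, and the 631 were not compared with that number. Over all groups DESeq2 called 289 and limma voom 123. The count was 120, 26 and 24 without NC_16 replicate 2, 4 and 5. Without any 1 of the WE_16 libraries between 4 and 6 genes were higher. The call of ENSGALG00000003594 was lost without NC_16 replicate 4 or WE_16 replicate 1 (adjusted p up to 0.107). Those of ENSGALG00000042686 and ENSGALG00000040730 were lost without NC_16 replicate 4 or 5 or WE_16 replicate 1, 3, 4 or 5. The former was also lost without NC_16 replicate 3 (up to 0.123) and the latter without NC_16 replicate 1 (up to 0.12). That of ENSGALG00000042686 was lost without the 3 libraries with the fewest detected genes (0.222). None of the 4 passed with all 50 libraries (0.101 to 0.648). All deposited HH16 libraries were already kept, so that fit added libraries of other stages only. There the log2 fold changes were -4.04, 2.17, 1.93 and -4.71 in the order named above. The calls of ENSGALG00000042686 and ENSGALG00000040730 were lost without a filter (0.0983 and 0.0599) and the former with limma voom (0.0920).

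Averaged over the stages, ENSGALG00000016680 was higher in GFP-positive cells by a log2 fold change of 3.26 ± 0.27 (SE, edgeR adjusted p = 5.59e-11), and ENSGALG00000042686 by 3.19 ± 0.28 (adjusted p = 1.14e-10). ENSGALG00000024379 (chromosome 13, 3147680 to 3166499) was lower, with a log2 fold change of -3.97 ± 0.43 (adjusted p = 1.3e-08). ENSGALG00000043234 (chromosome 14, 12510348 to 12511196) was lower, at -4.34 ± 1.02 (adjusted p = 0.00285). Genes called at 1 or more single stages numbered 657, and 119 of these were called at 3 or more stages, 18 higher and 101 lower. Called genes lay next to another gene called in the same direction in 338 cases, against 155 after shuffling within chromosomes (permutation p = 0.001, the smallest that 1000 shuffles can give), a test chosen after the data were seen. Of 2055 genes that passed, 675 were higher and 1380 lower, so that 67.2% were lower, and with the pool as a block 1184 were higher and 1447 lower. The call of ENSGALG00000043234 was lost without WE_10 replicate 2 (adjusted p = 0.0642) and without the 3 libraries with the fewest detected genes, of which that is 1 (0.0699), and with limma voom in place of edgeR (0.307).

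**Figure D2:**
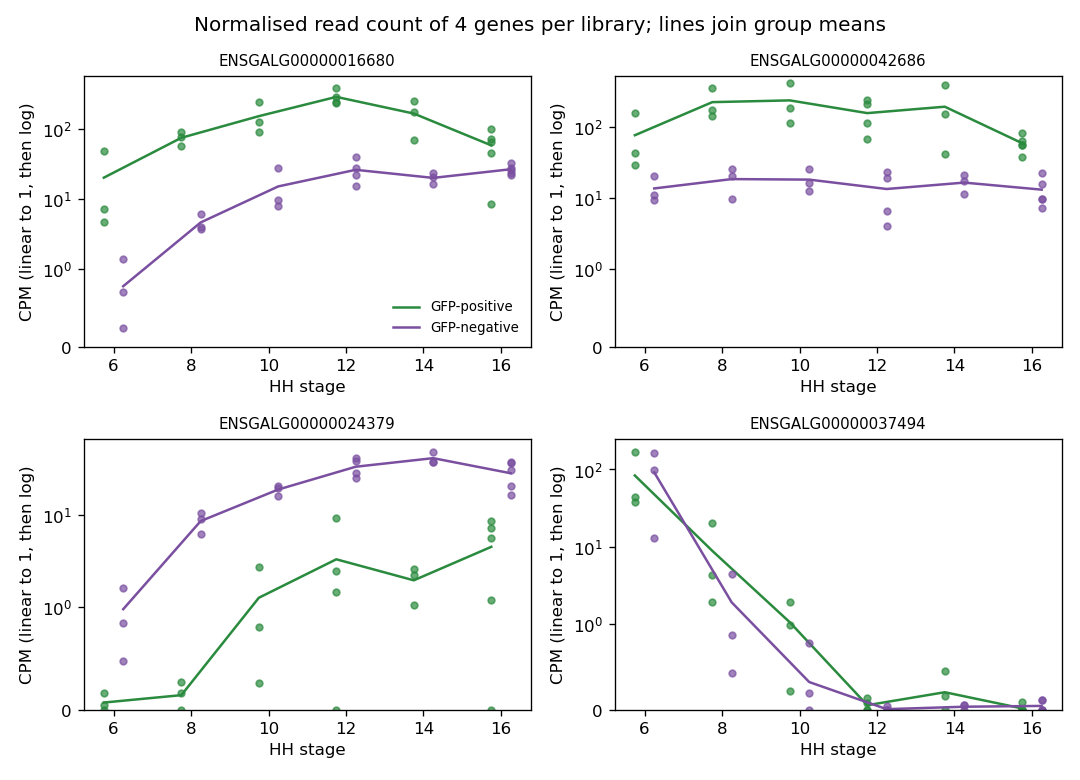
Normalised read count in CPM (y axis, linear to 1 and logarithmic above) of 4 genes against stage (x axis), with 1 point per library and lines joining group means. ENSGALG00000016680 and ENSGALG00000042686 have higher means in GFP-positive cells at every stage, ENSGALG00000024379 has lower means at every stage, and ENSGALG00000037494 has lower means at HH16 than at HH6 in both fractions.

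Between stages, the log2 fold changes between the fractions correlated across genes with a Pearson r of 0.50 for HH6 and HH8, 0.34 for HH8 and HH10, 0.44 for HH10 and HH12, 0.57 for HH12 and HH14, 0.30 for HH14 and HH16, and 0.04 for HH6 and HH16. Genes are not independent replicates, and these values were not tested.

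From HH6 to HH10 in GFP-positive cells, ENSGALG00000005628 (chromosome 20, 8340728 to 8372146) rose from 1.28 ± 0.880 CPM to 86.8 ± 21.4 CPM (SD, n = 3 each), a log2 fold change of 6.08 ± 0.73 (SE, edgeR adjusted p = 2.69e-06). ENSGALG00000053185 on chromosome 5 rose, with a log2 fold change of 6.22, and belongs to a run of 3 neighbouring genes between 24938602 and 24987701 that rose. ENSGALG00000006374 (chromosome 15, 8525645 to 8536564) fell from 44.9 ± 48.6 CPM to 0 reads in every HH10 library, at least 834-fold lower with 3 counts over the group as the floor, 323-fold without NC_6 replicate 2 and 509-fold without NC_10 replicate 4. ENSGALG00000032740 on chromosome 27 fell from 25.7 ± 19.1 CPM to 0.0365 ± 0.0632 CPM. In total 320 genes passed, 166 higher and 154 lower at HH10, and 569 passed with limma voom in place of edgeR, 190 higher and 379 lower. With the pool as a random effect added to voom 548 passed, 193 higher and 355 lower. The count was 120 and 101 without NC_6 replicate 1 and 2, and 205, 138 and 141 without NC_10 replicate 1, 2 and 4. It was 723 with the compared groups alone in the fit. It was 735 without the 3 libraries with the fewest detected genes, none of which belongs to these groups. The call of ENSGALG00000032740 was lost without any 1 of the 6 libraries (adjusted p up to 0.223) and without a filter (0.0850), and none of the 4 passed with all 50 libraries (0.0511 to 0.117).

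From HH10 to HH16 in GFP-positive cells, ENSGALG00000054309 (chromosome 2, 7989967 to 7999870) rose from 0 reads in every HH10 library to 21.7 ± 20.3 CPM (SD, n = 5), at least 403-fold higher with the same floor (edgeR adjusted p = 0.000184), 265-fold without NC_16 replicate 3 and 246-fold without NC_10 replicate 4. ENSGALG00000009844 (chromosome 5, 32480478 to 32485436) fell from 72.4 ± 51.1 CPM (n = 3) to 0.303 ± 0.330 CPM (adjusted p = 0.000326), and ENSGALG00000004582 (chromosome 15, 6330278 to 6334348) from 17.2 ± 13.8 CPM to 0.0116 ± 0.0260 CPM (adjusted p = 0.00249). In GFP-negative cells ENSGALG00000009844 stood at 747 ± 77.9 CPM at HH10 and 0.541 ± 0.459 CPM at HH16, and ENSGALG00000004582 at 143 ± 14.0 and 0.150 ± 0.0831 CPM (n = 3 and 5), a change that was not tested. ENSGALG00000017347 (chromosome 1, 197288212 to 197289402) rose from 0.190 ± 0.293 CPM to 381 ± 473 CPM. In total 1110 genes passed, 481 higher and 629 lower at HH16. The count was 704, 620 and 630 without NC_10 replicate 1, 2 and 4, and 201 with the compared groups alone in the fit. The call of ENSGALG00000017347 was lost with limma voom in place of edgeR (adjusted p = 0.367, and 0.339 with the pool as a random effect added), with the compared groups alone (0.0563) and without NC_10 replicate 1 or 4 (up to 0.0719). Over all alternatives that leave no library out in turn its adjusted p ran from 1.34e-06 to 0.476.

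From HH6 to HH16 in GFP-positive cells, ENSGALG00000037494 (chromosome 13, 15042075 to 15046001) fell from 83.6 ± 73.8 CPM (SD, n = 3) to 0.0191 ± 0.0426 CPM (n = 5), with edgeR adjusted p = 6.65e-09. ENSGALG00000005679 (chromosome 13, 13936846 to 13947085) fell from 45.1 ± 29.7 CPM to 0.0209 ± 0.0297 CPM (adjusted p = 1.33e-06). ENSGALG00000009002 (chromosome 1, 23415784 to 23554158) rose from 0 reads in every HH6 library to 26.8 ± 20.2 CPM, at least 499-fold higher and 328-fold without NC_6 replicate 1, and ENSGALG00000017347 rose from 0.112 ± 0.193 CPM to 381 ± 473 CPM. A run of 10 neighbouring tested genes on chromosome 2, between 32392815 and 32645922, fell. In total 2280 genes passed, 963 higher and 1317 lower at HH16, with 1417 without NC_6 replicate 2 and 906 with the compared groups alone in the fit. Higher genes numbered 636 and 641 without NC_6 replicate 1 and 3. The call of ENSGALG00000017347 was lost with limma voom in place of edgeR (adjusted p = 0.285, and 0.284 with the pool as a random effect added, within a range of 7.9e-08 to 0.353), and that of ENSGALG00000009002 with all 50 libraries (0.310).

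From HH6 to HH16 in GFP-negative cells, the same run of 10 genes on chromosome 2 fell. ENSGALG00000037494 fell from 91.7 ± 75.3 CPM (SD, n = 3) to 0.0483 ± 0.0662 CPM (n = 5, edgeR adjusted p = 2.64e-08), and ENSGALG00000007657 (chromosome 4, 12107176 to 12115777) from 66.3 ± 51.7 CPM to 0.0729 ± 0.163 CPM. ENSGALG00000015305 (chromosome 3, 67490385 to 67505356) rose from 0 reads in every HH6 library to 32.4 ± 11.4 CPM, at least 408-fold higher (adjusted p = 2.5e-06) and 230-fold without WE_6 replicate 1 or 2, and ENSGALG00000047152 on chromosome 1 rose from 0 reads to 18 ± 28.7 CPM, at least 227-fold higher, 66.4-fold without WE_16 replicate 1 and 128-fold without WE_6 replicate 1 or 2. Genes called in both fractions numbered 423 higher and 556 lower, where independent lists would share 48.1 and 85.1, and 4 were called in opposite directions. Across genes, the changes in the fractions had a Pearson r of 0.69, and the libraries of the fractions share pools of embryos by their titles. In total 1803 genes passed, 786 higher and 1017 lower at HH16. The count was 1169 and 922 without WE_6 replicate 2 and 3 and 1088 with the compared groups alone in the fit, and the call of ENSGALG00000047152 was lost without any 1 of the 3 HH6 libraries (adjusted p up to 0.0767).

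**Figure D3:**
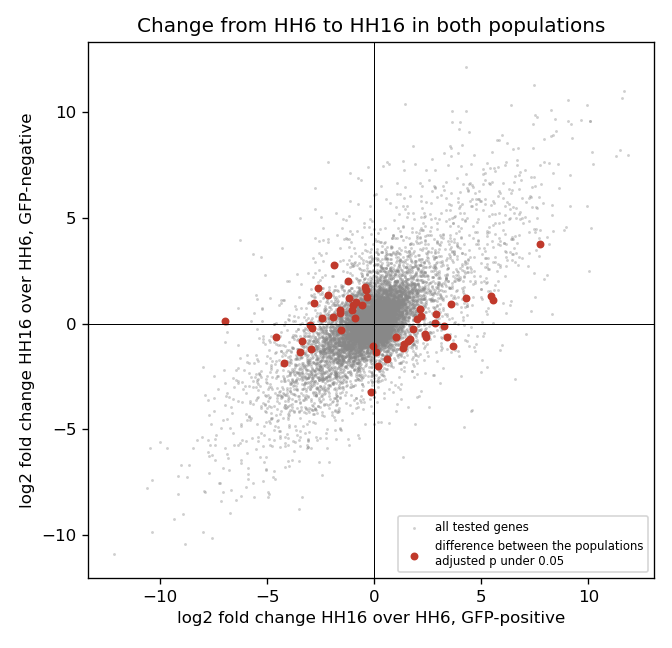
Log2 fold change from HH6 to HH16 in GFP-positive cells (x axis) and GFP-negative cells (y axis), with 1 point per tested gene and the 53 genes whose change differed between the fractions in red. Pearson's r across genes is 0.69.

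The difference between the fractions at HH16 was tested against that at HH6. ENSGALG00000008941 stood at 16 ± 18.2 CPM in GFP-positive and 1.52 ± 0.534 CPM in GFP-negative cells at HH6 (SD, n = 3 each), and at 4.41 ± 3.37 and 9.87 ± 7.25 CPM at HH16 (n = 5 each), a change of the log2 difference of -4.64 ± 0.93 (SE, edgeR adjusted p = 0.0209). ENSGALG00000017715 on chromosome 23 changed by -4.27, ENSGALG00000027213 by 4.72 and ENSGALG00000010461 on chromosome 6 by 4.45. In total 53 genes passed, 26 higher and 27 lower, and 217 passed with the pool as a block (68 higher and 149 lower), 24 with limma voom in place of edgeR, 4 with all 50 libraries and 2 with the compared groups alone in the fit. The count was 11, 12 and 2 without NC_6 replicate 1, 2 and 3, 18 without WE_6 replicate 3, 119 and 16 without NC_16 replicate 2 and 4, 24 and 34 without WE_16 replicate 2 and 3, and 99 without the 3 libraries with the fewest detected genes. Higher genes numbered 15 and 17 without WE_6 replicate 1 and 2 and 17 without WE_16 replicate 4 or 5, and lower genes 50 without WE_16 replicate 1. The call of ENSGALG00000008941 was lost without NC_6 replicate 3 or WE_6 replicate 2 (adjusted p up to 0.17), and those of ENSGALG00000027213, ENSGALG00000010461 and ENSGALG00000017715 in 12, 13 and 9 of the 16 fits that left out a library, among them those without any 1 of the NC_6 libraries (up to 0.311). None of the 4 calls passed with limma voom (0.0544 to 0.271), all 50 libraries (0.0960 to 0.710) or the compared groups alone (0.209 to 0.317). ENSGALG00000017715 was lost without the 3 libraries with the fewest detected genes (0.0561), ENSGALG00000010461 after thinning (0.0844), and ENSGALG00000027213 and ENSGALG00000010461 without a filter (0.0785 and 0.0626).

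Groups of genes were compared by chromosome and structure, in tests chosen after the data were seen. From HH6 to HH10 in GFP-positive cells, the 26 mitochondrial genes had a median log2 fold change of -0.65, and 1 of them was called lower and 0 higher. As a group they passed camera with a preset correlation (adjusted p = 7.33e-05), but not with an estimated correlation (0.669) or with fry (0.0789). From HH6 to HH16 in GFP-negative cells, the 43 chromosome W genes had a median of -0.83, and 1 of them was called lower and 0 higher. They passed camera with a preset correlation (adjusted p = 2.94e-06), but not with an estimated correlation (0.98) or with fry (0.230). In 2 of the 5 HH16 pools both libraries held at most 0.00264% of their reads on chromosome W. Of 96 such tests, 10 passed with the preset correlation, 0 with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.0789.

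**Figure D4:**
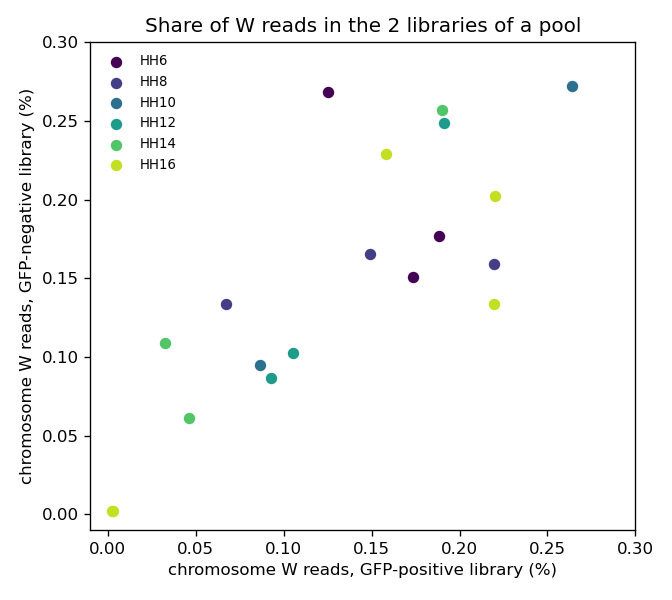
Share of counted reads on chromosome W in percent in the GFP-positive (x axis) and GFP-negative (y axis) library of each of 19 pools, coloured by stage. Both libraries of 2 HH16 pools lie between 0.00232% and 0.00264%, and the other kept libraries between 0.0323% and 0.272%.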

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

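The tests of chromosome W reads were chosen after the result was seen, and upper-quartile normalisation, thinning, quality weights, limma voom, leaving out the low-complexity libraries and the splits within pools were chosen after seeing the data.

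More genes were lower than higher in GFP-positive cells averaged over the stages, 67.2% of 2055. Unequal depth is argued against, since the share after thinning every library to equal depth was 64.9%. This lies above the bound of 60%, which was written after the counts of the comparisons had been seen and before this fit was run. The lower of the shares under DESeq2 size factors and upper-quartile normalisation was 68.7%. These scalings left the median log2 fold change over all tested genes near 0, at -0.01 under each, so that they moved too little to test scaling as the cause, which stays open. With the pool as a replicate block 1447 of 2631 genes were lower. This share is smaller than the 67.2% of the main fit and lies below 60%, so the imbalance was weaker with pools paired. Genes called higher rose from 675 to 1184 there, and genes called lower did not fall, from 1380 to 1447. A difference between the sorted populations themselves stays open as untested.

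Only 70 genes were called between the fractions at HH16, with 5 libraries per group. Leaving out the 3 low-complexity libraries gave 63, but 2 of them, NC_16 replicate 3 and WE_16 replicate 5, belong to the compared groups, which become smaller. These 3 libraries had the lowest quality weights (0.0920, 0.114 and 0.205). With limma voom in place of edgeR 123 genes were called, and 858 with library quality weights added to voom. Low-complexity libraries thus stay open as an explanation. The count rose to 143 with the sequencing set as a covariate and to 152 with the pool as a block, so that differences between sets or pools may account for part of the low count. Both settings raised counts at other stages too, for example to 708 and 740 at HH8. A smaller difference between the fractions at HH16 stays open as untested.

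Both libraries of 2 HH16 pools, NC_16 and WE_16 replicates 1 and 3, held between 0.00232% and 0.00264% of their reads on chromosome W, against a median of 0.150% over the kept libraries. Loss of W reads in a sequencing set is argued against, because in each of the 2 sets, and in each of the 3 sequencing runs, that held them another kept library reached at least 0.188%. In 1 of these runs only 1 other kept library, WE_10 replicate 2, was left to compare. The lowest Z share of these 4 libraries was 3.48%, above the highest of 2.77% in the other 6 HH16 libraries. This is what pools without female embryos may give, since W is carried by female birds only. The labels give about 20 heads per sample, with which such a pool would be rare, and this was not resolved.

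The difference between the fractions changed from HH6 to HH16 for 53 genes by a test of that change itself. All 50 libraries gave 4 genes, the compared groups alone 2 and limma voom 24, and another split of the libraries gave 144, as described below. The named ones were ENSGALG00000027213 (log2 change of 4.72), ENSGALG00000010461 (4.45), ENSGALG00000008941 (-4.64) and ENSGALG00000017715 (-4.27).

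In 59 groups of 4 or 5 libraries tested for a library far from the others, 8 were found. The test's rate of 1 in 20 holds for normally distributed values only, so the 8 cannot be compared with chance. WE_16 replicate 5 had the fewest genes with a read, 12498. WE_16 replicate 1 had the highest CPM of ENSGALG00000003594 (82.8) and ENSGALG00000047152 (69.0) and the lowest of ENSGALG00000007646 (18.9). NC_16 replicate 2 had the highest CPM of ENSGALG00000008941 (10.2) and ENSGALG00000004582 (0.0580), NC_16 replicate 3 of ENSGALG00000037494 (0.0953), and WE_16 replicate 2 of ENSGALG00000007657 (0.365). ENSGALG00000004582 and ENSGALG00000037494 each had 1 read over all NC_16 libraries, and ENSGALG00000007657 had 6 over all WE_16 libraries. With so few reads a library stands apart by counting alone.

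Other groupings of the same libraries were fitted for each comparison. With 3 libraries against 3 there are 10 groupings, too few for a share under 0.05. The real and highest other counts were 68 and 1 at HH6, 377 and 0 at HH8, 175 and 4 at HH10, 82 and 1 at HH14, and 320 and 1 for GFP-positive cells between HH6 and HH10. In each of these, 1 grouping, the real one, gave as many genes. For the other changes with stage all 56 groupings were fitted, those beyond the first 30 after these had been seen. From HH6 to HH16 in GFP-negative cells 1 of 56 gave as many genes (1803, next 205), a share under 0.05 that argues against chance. In GFP-positive cells 1 of 56 gave as many genes from HH6 to HH16 (2280, next 2142) and 2 of 56 from HH10 to HH16 (1110, the other 1934). The share of groupings was under 0.05 for both. It cannot exclude that a structure of the libraries gives such counts, since other groupings called 2142 and 1934 genes. The 2142 lies within the range of 1417 to 2351 that the real grouping gave with 1 library left out. Both large counts point to a structure of the libraries. The grouping with 1934 put NC_16 replicates 2 and 3 and NC_10 replicate 2, all of sequencing set MR, against the rest. Of the rest only NC_10 replicate 1 is of that set. The libraries it set apart also had the lowest quality weights of those compared (0.345, 0.0920 and 0.592, next 0.657). Whether set or library quality made this structure was not tested. The grouping with 2142 put NC_16 replicates 1, 4 and 5 against the other HH16 and the HH6 libraries, all of set MR but NC_6 replicate 1. With the sequencing set as a covariate 1646 genes were called from HH10 to HH16 and 2771 from HH6 to HH16.

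Where pools pair the libraries, the groupings to compare with are those that part every pool as the real one does. At HH12 there are 8 of these (331, next 6) and at HH16 there are 16 (70, next 0), of which 1, the real one, gave as many genes, too few for a share under 0.05. They number 4 each at HH6, HH8, HH10 and HH14. At HH10 and HH12 the libraries without a kept partner belong to no shared pool, and were kept on opposite sides in these groupings. For the average, 1 of 30 drawn of 1048576 such groupings gave as many genes (2055, next 17). That is a share under 0.05 among those drawn, which argues against chance. Over splits of the libraries made without regard to pools, 1 of 35 gave as many genes as the real 331 at HH12 (next 148), 1 of 30 drawn of 126 at HH16 (70, next 54) and 1 of 30 drawn for the average (2055, next 437). The one with 148 parts the libraries of set HLYH2BGX9 from the rest, and with the sequencing set as a covariate 598 genes were called at HH12.

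For the change of the difference from HH6 to HH16, 1 of 30 drawn of 128 groupings that part every pool gave as many genes (53, next 33). Over 30 drawn without regard to pools, 2 did, the other giving 144, which points to a structure of the libraries. The share was thus under 0.05 among the groupings drawn that part every pool, and not among those drawn without regard to pools. Chance stays open for this count.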

How the results depend on the processing

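Upper-quartile normalisation was run for the average only. Quality weights, limma voom alone, the sequencing run, the thinned and low-complexity fits, and those without chromosomes Z and W were chosen after seeing the data. In the order HH6, HH8, HH10, HH12, HH14, HH16, the main counts of genes between the fractions were 68, 377, 175, 331, 82 and 70. All 12 counts stayed within 1.5 times under DESeq2 size factors, the 1 CPM filter, thinning, and without Z and W. Without a filter 1 changed, to 116 at HH10. Where the cause of a change is not named, the cause was not tested.

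All 50 libraries gave 11, 9, 78, 156, 1 and 4 genes, 1217 for the average, 35 from HH6 to HH10, 608 from HH10 to HH16, 3460 (GFP-positive) and 719 (GFP-negative) from HH6 to HH16, and 4 for the change of the difference. At HH14 and HH16 all deposited libraries were kept, so that the extra libraries acted there only through the fit shared by all groups. A test against a 1.5-fold change, stricter by construction, gave 28, 170, 51, 142, 26 and 20 genes, 694 for the average, 142, 462, 1355 and 843 between stages, and 0 for the change of the difference, where that edgeR test had 935 at an unadjusted p under 0.05 and DESeq2 called 206. DESeq2 gave 238, 712, 611, 642, 273 and 289, with 671 from HH6 to HH10, 1774 from HH10 to HH16 and 206 for the change of the difference.

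The sequencing set as a covariate gave 172, 708, 409, 598, 214 and 143, with 497 from HH6 to HH10 and 143 for the change of the difference. The sequencing run as a covariate gave 193, 815, 417, 684, 241 and 120, with 614 from HH6 to HH10 and 142 for the change of the difference. With limma voom in place of edgeR the counts were 338 at HH10, 155 at HH14, 123 at HH16, 569 from HH6 to HH10 and 24 for the change of the difference. With the pool as a replicate block the counts were 217 at HH6, 740 at HH8, 212 at HH14, 152 at HH16, and 217 for the change of the difference, and no other total moved by over 1.5 times. For changes with stage the pool could enter only as a random effect in limma voom, which gave 548 from HH6 to HH10, close to the 569 of voom alone. The block ended 4 of 32 named calls, those of ENSGALG00000002263 at HH10, ENSGALG00000053511 and ENSGALG00000015253 at HH12 and ENSGALG00000039245 at HH14, and changed no other. The random effect in voom ended 2 of 16, both of ENSGALG00000017347, which voom alone ended too. The block moved the median of all genes at HH10 to 0.11, and all 50 libraries moved that at HH8 to 0.10 (log2). Only the compared groups in the fit gave 750 at HH8, 0 at HH16 (631 with edgeR at an unadjusted p under 0.05, where DESeq2 over all groups called 289), 723 from HH6 to HH10, 201 from HH10 to HH16, 906 and 1088 from HH6 to HH16 in GFP-positive and GFP-negative cells, and 2 for the change of the difference. The fit of only the compared groups could not differ for the average, which uses all groups. Without any difference a share of 0.05 of tested genes would fall under that unadjusted p. The 631 are thus no sign of a difference by themselves.

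Without the 3 low-complexity libraries the counts were 177 at HH6, 705 at HH8, 657 at HH12, 217 at HH14, 735 from HH6 to HH10 and 99 for the change of the difference. Only the last of these comparisons uses groups that hold any of the 3. In the others leaving them out acted only through the fit shared by all groups. Library quality weights in limma voom gave 228, 4762, 274, 2557, 621 and 858, with 3408 for the average, 1320, 2793 and 5080 between stages in GFP-positive cells and 410 for the change of the difference.

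Leaving out each library in turn, which lowers n, gave 32 to 59 at HH6, 166 to 295 at HH8, 14 to 267 at HH10, 153 to 353 at HH12, 14 to 69 at HH14 and 24 to 120 at HH16. The ranges were 101 to 260 from HH6 to HH10, 620 to 1112 from HH10 to HH16, 1417 to 2351 and 922 to 1669 from HH6 to HH16 in GFP-positive and GFP-negative cells, and 2 to 119 for the change of the difference. The average stayed between 1809 and 2253.

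Of 48 named genes by comparison, 24 kept their call in every such fit and 24 lost it in at least 1, and none reversed under any alternative run. All 50 libraries ended 29 of the 48 calls, the compared groups alone 14 of 44, limma voom 13, the test against a 1.5-fold change 13, no filter 8, quality weights in voom 5, leaving out the low-complexity libraries 3 and thinning 1, and each gene's loss with all 50 libraries, the compared groups, voom, no filter, the low-complexity libraries or thinning is given with its comparison. The 5 lost with quality weights were ENSGALG00000016680 and ENSGALG00000008941 at HH6, ENSGALG00000043234 in the average and ENSGALG00000017347 in both changes to HH16. The 13 lost against a 1.5-fold change were ENSGALG00000008941 and ENSGALG00000027213 at HH6, ENSGALG00000053511 and ENSGALG00000015253 at HH12, ENSGALG00000012290 and ENSGALG00000039245 at HH14, ENSGALG00000042686 and ENSGALG00000040730 at HH16, ENSGALG00000032740 from HH6 to HH10 and the 4 of the change of the difference. DESeq2, its size factors, the 1 CPM filter, the sequencing set and the sequencing run ended 0. The gene list tests were not run, because the identifiers could not be matched to symbols. Depth limits genes near 0 reads, and the spread between libraries limits small changes at single stages.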

Other observations

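The tests in this part were chosen after the result was seen. Runs of neighbouring genes changed together with stage. From HH6 to HH16, 58 runs of 3 or more neighbouring called genes in one direction were found in GFP-positive cells and 39 in GFP-negative cells. In GFP-positive cells 4 neighbouring genes on chromosome 27 between 6243545 and 6290582 fell, and 5 genes on chromosome 7 between 17833099 and 17959918 rose. In GFP-negative cells 5 genes on chromosome 27 between 6226468 and 6290582 fell. In both fractions 3 genes on chromosome 1 between 44000044 and 44202174 rose, and so did 3 on chromosome 14 between 12503627 and 12511196. Neighbouring pairs numbered 348 and 243 against 177 and 108 after shuffling (permutation p = 0.001 for each, the smallest 1000 shuffles can give). At HH6 and HH16 no neighbouring pair was called between the fractions, with 0.122 and 0.258 expected.

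The share of chromosome W reads in the GFP-positive library of a pool went with that in its GFP-negative library. Over 19 pools Pearson's r was 0.785 (permutation p = 0.000100, adjusted over 4 relations 0.0002) and Spearman's rho 0.751 (permutation p = 0.00037, adjusted 0.00074), and r was 0.663 without the 2 pools farthest from the median. Within the 10 pools of the set MR, which joins 3 sequencing runs, r was 0.682 (permutation p = 0.0322) and rho 0.576 (permutation p = 0.0872), and r was 0.256 without the 2 farthest, so that there the relation rests on those pools. The other sets held too few pools. For chromosome Z, r was 0.909 over all pools (permutation p = 1e-05, the smallest 100000 resamples can give) and 0.906 within MR (permutation p = 0.00049). This is consistent with the same embryos standing behind both libraries of a pool, as a hypothesis.

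The 8 libraries outside the filtered table were compared with the mean of each group across genes. NC_6 replicate 4 held 512123 reads and correlated with its own group at 0.250 and most with WE_12, at 0.310. WE_6 replicate 4 correlated with its own group at 0.947 and with WE_12 at 0.962, and NC_8 replicate 4 at 0.810 and 0.820. WE_10 replicate 1 correlated with its own group at 0.849 and with WE_8 at 0.888, and WE_12 replicate 4 at 0.919 and 0.929. WE_8 replicate 4 correlated with its own group at 0.929 and with NC_12 at 0.982, NC_10 replicate 3 with its own group at 0.964 and with NC_8 at 0.985, and NC_12 replicate 5 most with its own group, at 0.981.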
